A study of Arabidopsis thaliana with 32 samples.

How the data were processed

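The files hold an RPKM table of 12 RNA-seq libraries (wild type and fip37 LEC1:FIP37, mock or NAA, 3 replicates each) and 7 lists of m6A peaks from Arabidopsis thaliana seedlings, 15 days old per the labels. The m6A lists come from 10 immunoprecipitated libraries with their inputs: wild type with mock (2 replicates), wild type with NAA (2), tmk4 with NAA (2), 35S:FIP37 (2) and 35S:FIP373A (2). The labels give no treatment for the 35S lines. In the RPKM table the columns named for the genotype alone were read as the mock libraries, and 0 columns were left unassigned. Coverage tracks in bigWig format were not used here.

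The RPKM values were computed by the authors per gene and library, per the labels, after alignment with STAR 2.5.3a to TAIR10, per the submitters' processing notes. The counting tool, its annotation, its use of strand and its treatment of reads that match several genes are not given in the sources used here. The libraries were strand-specific, made with dUTP, per the labels' protocols. For the 4 wild-type peak lists the authors ran MACS 2.2.6 on each replicate against its own input, without model building, with fragments extended to 200 nt, 1 duplicate tag kept per position and a q-value threshold of 0.05, per the file headers. These lists give the pileup signal at the summit, the -log10 p-value and q-value, and the fold enrichment over the input's local background, as deposited and per the file headers. For the other 3 lists (tmk4, 35S:FIP37 and 35S:FIP373A) the authors deposited 1 list per genotype, with peaks on exons in steps of 50 nt, an enrichment score and a column headed score. From its values the latter was read as a p-value or q-value of the authors' caller. That caller, its settings, the use of inputs and the way replicates were combined are not given in the sources used here. Peaks of these 3 lists were used as whole spans from start to end.

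Read totals are not given with the RPKM table. The relative depth of the libraries was taken from the whole-read steps of low values and lay between 83.6% and 152% of the first wild-type mock library. With no read totals no counting interval is given for RPKM values, and an exact 0 means only that a gene is listed at 0. For the wild-type m6A libraries the file headers give 6420713 to 6714976 immunoprecipitated and 6866684 to 7459284 input tags kept. Shares of peaks are given with 95% Wilson intervals, which cover counting error only.

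Transcript levels were compared with limma 3.58.1 in R 4.3.3 (limma-trend with empirical Bayes moderation) on log2(RPKM + 1), so fold changes understate those of low genes. One model held all 12 libraries in 4 groups of 3, which share 1 estimate of the spread per gene, and 18072 of 34262 genes with a mean of at least 1 RPKM were tested. The contrasts were NAA against mock within each genotype, fip37 LEC1:FIP37 against wild type within each treatment, and the difference of the 2 NAA effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose" or "fell" is said only of called genes. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01 and again with the correlation estimated per list, adjusted over 85 tests (17 lists with at least 3 tested genes, 5 contrasts). Of these, 35 were called at the preset correlation and 1 with the estimated one.

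Peaks counted as shared when they overlapped by at least 50% of the shorter peak. A wild-type peak was called reproducible when both replicates held it. It was NAA-only or mock-only when it also overlapped no peak of either list of the other treatment, not even by 1 bp. A summit was assigned to the gene that holds it by the TAIR10.1 annotation, which was used for names and this assignment only; between 94.85% and 95.24% of the wild-type summits lay in 1 gene. Of the 34262 gene identifiers 32548 matched that annotation. Coordinates are those of the files (TAIR10, counted from 1). Lists of genes were compared with peaks by Fisher's exact test, two-sided, adjusted over the gene lists within each set of peaks. Transcript changes of genes with and without peaks were compared as the difference of medians within 20 bins of mean expression, with 100000 permutations within bins (two-sided). The scores of peaks are the authors' and were used only to rank peaks within a list. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 was used for peaks and figures.

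The comparisons, the 19 gene lists, the rule for named genes and all alternatives not said to be chosen after the data were seen were fixed before the data were examined. The lists, with 308 members in all, cover auxin biosynthesis, auxin conjugation and oxidation, Aux/IAA, SAUR, other early auxin response, auxin transport, auxin perception and ARF, m6A writers, erasers and readers, shoot meristem, ethylene, cytokinin response and metabolism, defence and jasmonate, heat shock, photosynthesis, circadian clock, root markers, seed and embryo markers, flowering, and cell division. The annotation gave the list's name to 295 members, no such name to 13 and the name to another locus for 0. Named genes are FIP37 in every library, then per contrast the 10 called genes with the largest rise and the 10 with the largest fall among those with at least 5 RPKM in the higher group and replicates that do not overlap, and the called members of each list with the 4 smallest adjusted p. The results of 2 genes that fell under this rule are not reported here. Members of the auxin biosynthesis, Aux/IAA, conjugation and m6A lists with an NAA-only or mock-only peak were also named, as were the 10 peaks of each kind with the highest mean score. The text names a part of these.

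The alternatives were a pseudocount of 0.1, no expression filter or a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, the replicate number as a block, a fit of only the groups compared, robust empirical Bayes, a 2-fold minimum, and leaving out each replicate in turn. For peaks they were an overlap of 1 bp or 80% of the shorter peak, the higher-scoring 50% of each list, equal list lengths, a peak in either replicate list, and leaving out each replicate. Added after the data were seen were a fit without the third wild-type NAA library and the second mock library labelled fip37 LEC1:FIP37, bins of the wild-type mock mean, peak tests at matched expression, and peak and transcript comparisons without the third wild-type NAA library or with median-ratio scaling. The scripts were tested on simulated data. For NAA in wild type, 80% of 100 genes changed by 1 on the log2 scale and 96% of 100 changed by 2 were called among 18072 genes, with 7 false calls. For 4000 simulated genes the permutation test gave p under 0.05 in 3 of 100 null runs and estimated a planted shift of 0.2 as 0.168, and Fisher's test gave it for 9 of 200 null lists. The position of peaks along transcripts and their sequence motifs were not analysed here.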

Results

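The series measured m6A, the methylation of adenosine in RNA, and transcript levels in Arabidopsis thaliana seedlings. It comprised 32 libraries in 14 groups. Of these, 20 were m6A immunoprecipitates and their inputs, with 2 replicates per group, from wild type under mock or auxin treatment, the tmk4 mutant with auxin, and the lines 35S:FIP37 and 35S:FIP373A. The other 12 were RNA-seq libraries, with 3 replicates per group, from wild type and from plants labelled fip37 LEC1:FIP37, each under mock or auxin treatment. The auxin was NAA, a synthetic auxin, given at 50 µM for 3 h. FIP37 is a subunit of the complex that writes m6A, and TMK4 is a receptor-like kinase of auxin signalling. The line labelled fip37 LEC1:FIP37 is named for a fip37 mutant that carries FIP37 behind LEC1, a promoter of embryos. The RPKM table carries no read totals. From the whole-read steps of its low values, the libraries held between 83.6% and 152% of the reads of the first wild-type mock library. Between 22694 and 23359 genes were above 0 in each library, and 18072 genes with a mean of at least 1 RPKM were tested. For the wild-type m6A libraries, the peak headers give between 22553583 and 24681870 immunoprecipitated tags per replicate, of which 26.5% to 29.8% were kept after duplicates were removed. The labels call the libraries replicates without saying that they came from separate plant cultures, so limma's p-values measure the spread between these samples. Fisher's exact tests and the permutation tests compare genes, which are not independent replicates. Their p-values hold no spread between libraries.

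FIP37 transcripts were higher, not lower, in the libraries labelled fip37 LEC1:FIP37. FIP37 (AT3G54170) stood at 11.6 ± 0.622 RPKM (mean ± SD, n = 3) in wild-type mock and 79.0 ± 18.4 in mock libraries of that label. The log2 fold change was 2.64 (SE 0.29, adjusted p = 3.83e-05), and it was 2.18 (SE 0.29, adjusted p = 0.000102) between the NAA groups. Every library with the label held at least 57.9 RPKM, against at most 23.3 in wild type. RPKM per gene does not separate transcripts of a transgene or a mutant allele from others, so every direction below that compares these libraries with wild type is a comparison of labels. The neighbouring gene CDKB1-1 (AT3G54180) ranged from 2.66 to 3.21 RPKM in wild type and from 3.68 to 5.64 in the libraries labelled fip37 LEC1:FIP37. NAA did not change FIP37 detectably in either genotype with all libraries included. Its wild-type log2 fold change was 0.56 (SE 0.29, adjusted p = 0.253), and without the third NAA library it was 0.87 (adjusted p = 0.0272). In the libraries labelled fip37 LEC1:FIP37 it was 0.11 (adjusted p = 0.997), and it changed sign without the first mock library (-0.09) or the second NAA library (-0.14).

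**Figure D1:**
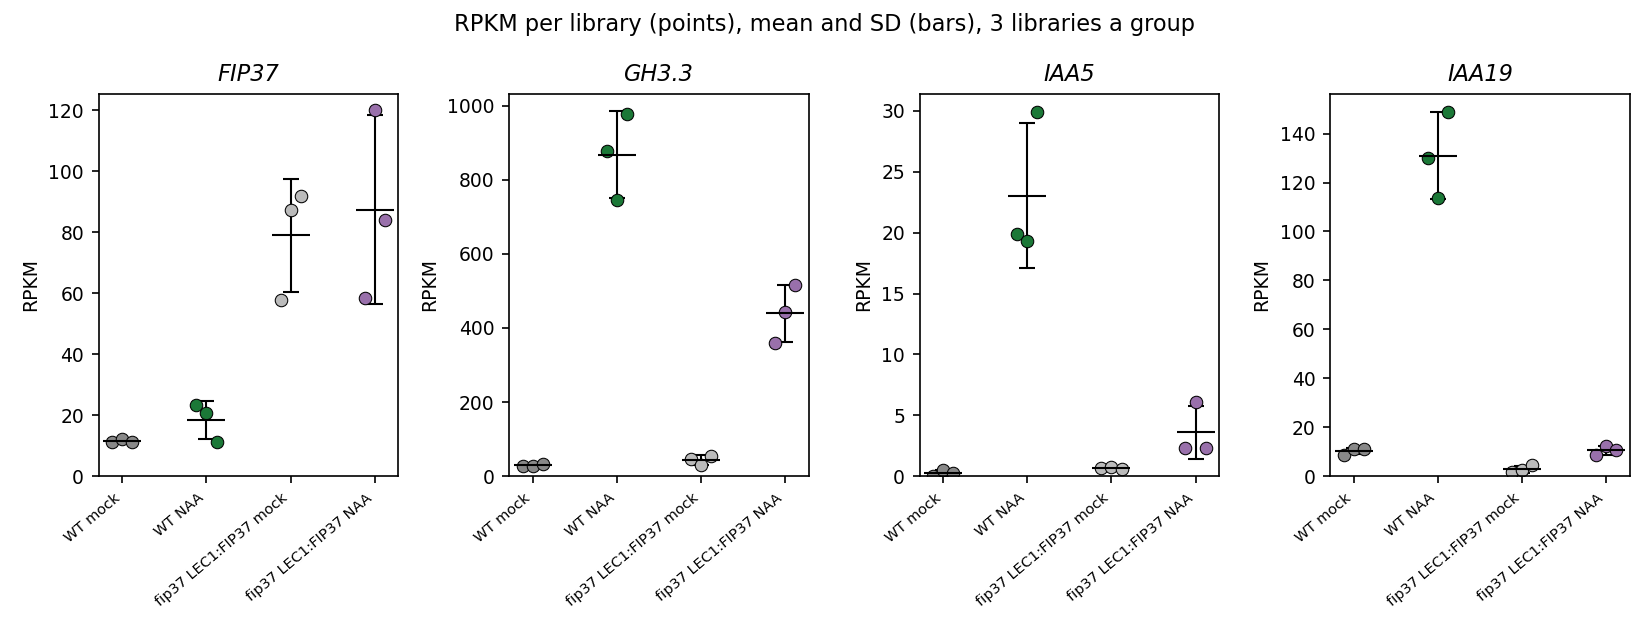
RPKM of FIP37, GH3.3, IAA5 and IAA19 in each of the 12 RNA-seq libraries, by group, with points for libraries and bars for the mean ± SD of 3. FIP37 lay at or above 57.9 RPKM in each library labelled fip37 LEC1:FIP37 and at or below 23.3 in each wild-type library.

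NAA raised the transcripts of early auxin response genes in wild type, the comparison that asks how seedlings respond to auxin. GH3.3 (AT2G23170), which encodes an enzyme that joins auxin to amino acids, went from 29.6 ± 2.40 to 867 ± 118 RPKM (n = 3 per group; log2 fold change 4.82, SE 0.21, adjusted p = 4.95e-07). GH3.2 (AT4G37390) went from 8.44 ± 0.743 to 272 ± 85.9 (4.81, SE 0.28, adjusted p = 4.2e-06). IAA5 (AT1G15580), an auxin-induced repressor of auxin signalling, rose from 0.266 ± 0.252 to 23.0 ± 5.97 (4.24, SE 0.28, adjusted p = 7.72e-06). IAA19 (AT3G15540) rose from 10.3 ± 1.36 to 131 ± 17.8, and IAA1 (AT4G14560) from 18.7 ± 1.51 to 224 ± 16.0. Among the genes that fell were those for the iron transporter IRT1 (AT4G19690; 11.5 ± 2.22 to 0.783 ± 1.33) and the iron reductase FRO2 (AT1G01580; 6.27 ± 1.03 to 0.547 ± 0.0786). The aquaporin gene TIP2;3 (AT5G47450) also fell, from 19.2 ± 2.05 to 1.65 ± 0.611 RPKM. In all, 1509 of the 18072 genes were called at an adjusted p under 0.05, 605 higher and 904 lower, and 429 of them changed at least 2-fold, 265 higher and 164 lower. With median-ratio scaling the split was 880 higher and 689 lower.

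Of the fixed gene lists, those of auxin response moved most with NAA in wild type. In the SAUR list, genes for small auxin-up RNAs, 16 of 20 tested members rose and 4 were not called (19 rose adjusted over the list alone). SAUR68 (AT1G29490) rose by 3.25, SAUR15 (AT4G38850) by 3.07 and SAUR9 (AT4G36110) by 2.38 on the log2 scale. For this list camera gave an adjusted p = 7.45e-29, and adjusted p = 0.0703 with an estimated correlation. In the Aux/IAA list 15 of 24 rose and 9 were not called (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 1e-16, and adjusted p = 0.0703 with an estimated correlation). In the list of auxin conjugation and oxidation 6 of 11 rose (6 adjusted over the list alone), GH3.1 (AT2G14960, 2.56) and GH3.5 (AT4G27260, 1.81) among them (camera adjusted p = 2.09e-08, and adjusted p = 0.187 with an estimated correlation). In the list of other early auxin response 11 of 17 rose and 6 were not called (13 rose and 2 fell adjusted over the list alone). LBD29 (AT3G58190) rose by 1.97 and HAT2 (AT5G47370) by 1.78 (camera adjusted p = 3.37e-12, and adjusted p = 0.0703 with an estimated correlation). The counts of calls in SAUR19 to SAUR24 and in SAUR61 to SAUR68 are uncertain, as these are near-identical copies and the counting of reads that match several of them is not given in the sources used here.

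Genes for auxin biosynthesis, the subject named in the series title, moved both ways with NAA in wild type. NIT4 (AT5G22300) rose from 7.09 ± 1.46 to 29.9 ± 1.27 RPKM (n = 3 per group; log2 1.95, SE 0.19, adjusted p = 0.000127) and NIT2 (AT3G44300) from 76.1 ± 14.1 to 236 ± 16.6 (1.63, SE 0.20, adjusted p = 0.000574). TAA1 (AT1G70560), which makes the precursor of auxin, fell from 7.68 ± 0.856 to 3.75 ± 0.707 (-0.87, SE 0.16, adjusted p = 0.0067), and YUC6 (AT5G25620) fell as well (-0.85, SE 0.13, adjusted p = 0.00297). AMI1 (AT1G08980), named after its values were seen, fell by 0.61 (adjusted p = 0.0447). The remaining 15 of 20 tested members were not called (3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.464). In the auxin transport list 4 of 17 rose and 1 fell, PILS3 (AT1G76520) at 0.98 among them (5 and 3 adjusted over the list alone; camera adjusted p = 0.151). Of those that rose, LAX2 (AT2G21050) lost its call without the first or second mock library (adjusted p = 0.054 and 0.0633), and ABCB4 (AT2G47000) without the first, the second or the third mock or the first NAA library (0.0929, 0.0819, 0.056 and 0.0542). The median of that list was -0.04, while its mean was 0.18 and its test pointed up. In the list of auxin perception and ARF factors 1 of 22 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.339). These 3, ARF19 (AT1G19220), TIR1 and AFB1, each lost the call without any 1 of the 3 mock libraries or the first or second NAA library (adjusted p = 0.0705 to 0.157). AFB1 also lost it without any mock library or the third NAA library of the other genotype (0.0501 to 0.0571).

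In the list of m6A writers, erasers and readers 2 of 22 rose with NAA in wild type and 20 were not called (2 adjusted over the list alone; camera adjusted p = 0.832; median -0.09, mean 0.02). The demethylase gene ALKBH10B (AT4G02940) went from 17.8 ± 2.18 to 43.8 ± 24.2 RPKM (n = 3 per group; log2 1.14, SE 0.26, adjusted p = 0.0216), with 71.8 RPKM in the third NAA library against 29.7 and 30.03 in the other two. Without that library its log2 fold change was 0.72 (adjusted p = 0.00177). Its call was lost without the first, the second or the third mock library (adjusted p = 0.0676, 0.0881 and 0.062). The reader gene ECT4 (AT1G55500; 0.68, SE 0.15, adjusted p = 0.0203) lost its call without the same libraries (adjusted p = 0.0803, 0.0555 and 0.0749). In the ethylene list 3 of 11 fell (5 adjusted over the list alone; camera adjusted p = 0.0304, and adjusted p = 0.673 with an estimated correlation), ACO1 (AT2G19590) from 7.55 to 2.67 RPKM. ACO4 lost its call without any mock library, the first or second NAA library, or the third NAA library of the other genotype (0.0555 to 0.134). Among the root markers 2 of 8 fell (4 adjusted over the list alone; camera adjusted p = 0.00558, and adjusted p = 0.305 with an estimated correlation). Both calls, PYK10 and COBL9, ended without the first or the third mock or the second NAA library, and that of PYK10 also without the first NAA library (adjusted p = 0.0625 to 0.0858). In the cytokinin list 2 of 10 rose (2 adjusted over the list alone; camera adjusted p = 0.16), with CKX6 (AT3G63440) at 1.13. The other, CKX1, lost its call without the second mock or the second NAA library (adjusted p = 0.0606 and 0.0538).

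The third wild-type NAA library stood apart from the others of its group. In it, 1711 tested genes lay at least 2-fold from the mean of the other two, against 358 and 321 for those. The genes named for it here were chosen after their values were seen. HSP17.6A (AT5G12030), a small heat-shock protein gene, stood at 79.0 RPKM in it against 2.88 and 2.62, and HSP101 (AT1G74310) at 32.0 against 5.38 and 3.45. The immune-response kinase gene FRK1 (AT2G19190) stood at 2.16 RPKM in it against 103 and 79.3. FRK1 was also low in the third wild-type mock library, at 5.86 RPKM against 56.9 and 26.8 in the first and second. SAUR genes of the third NAA library had responded to NAA, with a median 2.575 above the mock mean on the log2 scale. Without this library limma called 4119 genes (1943 higher, 2176 lower), which include 1483 of the 1509. Without the first, the second or the third mock library it called 651, 632 and 477, and without the first or second NAA library 1005 and 679. The fits without a mock or the second NAA library called more genes higher than lower (333 and 318, 339 and 293, 284 and 193, and 418 and 261). Each library left out costs a replicate, so a lost call alone does not mark a fragile gene. No gene of the heat shock list was called with NAA in wild type by limma (1 of 9 rose at an unadjusted p under 0.05; 0 adjusted over the list alone; camera adjusted p = 0.0518).

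**Figure D2:**
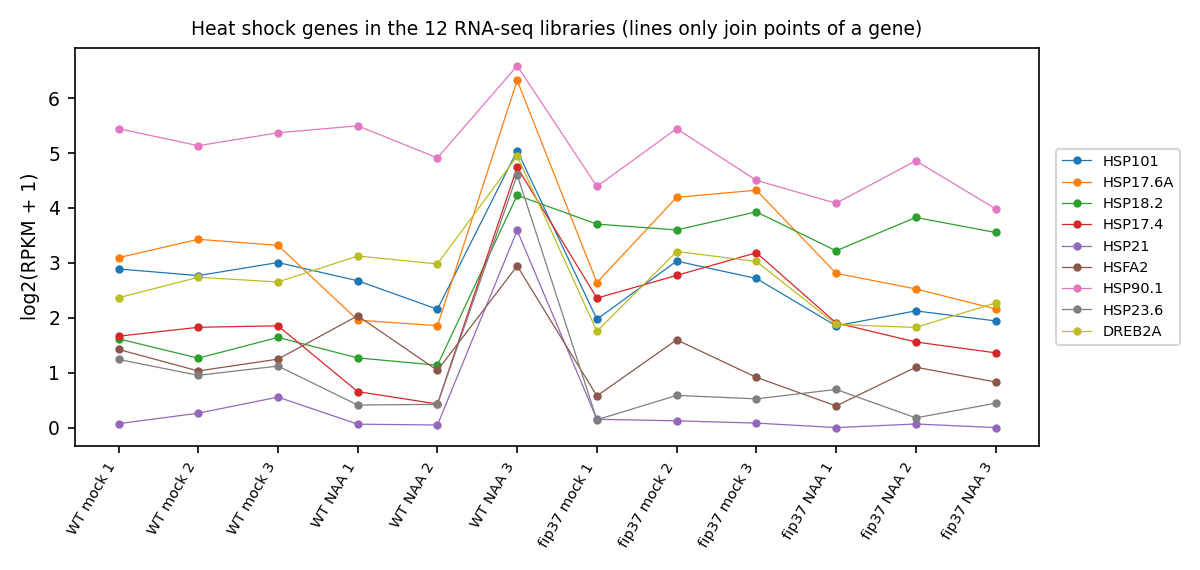
Transcript levels of the 9 genes of the heat shock list, as log2(RPKM + 1), in each of the 12 RNA-seq libraries; each line joins the points of a gene. In the third wild-type NAA library HSP17.6A reached 79.0 RPKM, against 2.88 and 2.62 in the other two of the group.

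Auxin response genes also rose with NAA in the libraries labelled fip37 LEC1:FIP37, but fewer of them. GH3.3 went from 44.2 ± 13.5 to 439 ± 77.7 RPKM (n = 3 per group; log2 3.32, SE 0.21, adjusted p = 3.95e-05) and GH3.2 from 17.2 ± 6.96 to 147 ± 12.3 (3.11, SE 0.28, adjusted p = 0.000925). MAKR4 (AT2G39370) rose from 3.39 to 16.8 (2.06, SE 0.25, adjusted p = 0.00382) and IAA29 (AT4G32280) from 5.02 to 19.1 (1.70, SE 0.20, adjusted p = 0.00275). PUCHI (AT5G18560), a transcription factor gene of lateral root formation, rose from 0.176 to 2.22 RPKM here (1.45, SE 0.15, adjusted p = 0.00158) and stood at 0.819 and 0.952 in wild type. AT5G06730 fell from 29.0 to 9.08 RPKM (-1.60, SE 0.21, adjusted p = 0.00538). In all 79 genes were called, 68 higher and 11 lower, of which 50 changed at least 2-fold. The count was 31 without the second mock library, 51 without the third, 37 without the second NAA library, 51 without the third, and 201 (130 higher, 71 lower) without the third wild-type NAA library, which shares the estimate of spread. Of the 68 that rose here 45 had also risen in wild type, where 2.28 would be shared by independent lists (Fisher's exact test, two-sided p = 3.2e-50). Of the 11 that fell, 2 had fallen in wild type (0.55 by independence, Fisher's exact p = 0.102).

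By list, NAA in the libraries labelled fip37 LEC1:FIP37 raised 6 of 24 Aux/IAA genes (10 adjusted over the list alone; camera adjusted p = 1.53e-17, and adjusted p = 0.0703 with an estimated correlation). IAA19 and IAA30 lost their calls without the second NAA library of that label (adjusted p = 0.0516 and 0.0546). It raised 5 of 11 conjugation and oxidation genes (6 adjusted over the list alone; camera adjusted p = 2.89e-09, and adjusted p = 0.158 with an estimated correlation). Of the other early auxin response genes 7 of 17 rose (11 adjusted over the list alone), GATA23 (AT5G26930, 1.59), LBD18 (AT2G45420, 1.55) and HAT2 (1.38) among them. Camera gave this list an adjusted p = 3.99e-23, and the call held with an estimated correlation (adjusted p = 0.045). In the auxin transport list 2 of 17 rose (8 adjusted over the list alone; camera adjusted p = 3e-07, and adjusted p = 0.202 with an estimated correlation), of which LAX2 lost its call without any 1 of the 6 libraries of that label (adjusted p = 0.0514 to 0.0817). No SAUR gene of 20 was called by limma (6 rose at an unadjusted p under 0.05; 2 rose adjusted over the list alone). The list's median was 0.39 and camera gave an adjusted p = 7.76e-09, and adjusted p = 0.27 with an estimated correlation. No gene of 20 in the auxin biosynthesis list was called by limma over all genes (13 lower and 0 higher at an unadjusted p under 0.05), while 11 fell adjusted over the list alone. Its median was -0.58 (camera adjusted p = 1.52e-08, and adjusted p = 0.202 with an estimated correlation). In the defence and jasmonate list limma called 0 of 21 (7 lower at an unadjusted p under 0.05; 0 adjusted over the list alone; median -0.59; camera adjusted p = 4.22e-06, and adjusted p = 0.27 with an estimated correlation).

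The change with NAA differed between the genotypes at 306 genes by a test of the difference itself, 115 with a higher and 191 with a lower log2 fold change in the libraries labelled fip37 LEC1:FIP37. IAA5 rose to 23.0 ± 5.97 RPKM in wild type but to 3.61 ± 2.19 there (difference of log2 fold changes -2.89, adjusted p = 0.00648, n = 3 per group). SAUR68 stood at 14.5 ± 4.80 RPKM with NAA in wild type and at 0.258 there (-3.29, adjusted p = 0.00146), and SAUR15 at 22.2 ± 3.79 and 3.97 (-2.83, adjusted p = 0.00146). IAA1 reached 224 ± 16.0 and 27.3 ± 5.73 (-2.22, SE 0.24, adjusted p = 0.00271). NIT4 rose with NAA in wild type and stood at 41.3 ± 11.5 and 21.8 ± 3.27 RPKM in mock and NAA there (-2.82, adjusted p = 0.00146), and NIT2 at 778 ± 174 and 462 ± 96.9 (-2.38, adjusted p = 0.00363). In the other direction, FRO2 fell with NAA in wild type and lay at 0.225 and 0.255 RPKM there (2.26, adjusted p = 0.00146). At that mock level FRO2 could hardly fall on the scale of log2(RPKM + 1), so its difference mostly restates the fall in wild type. PUCHI changed more there (1.34, adjusted p = 0.0123). With quantile normalization 493 genes were called, 257 higher and 236 lower. Without 1 library the count was 117, 86 and 68 for the first, the second and the third wild-type mock library, and 149 and 2231 for the second and the third wild-type NAA library. Among the libraries labelled fip37 LEC1:FIP37 it was 114 without the second mock library, and 160, 153 and 147 without the first, the second and the third NAA library.

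In the SAUR list 9 of 20 genes had a lower change with NAA in the libraries labelled fip37 LEC1:FIP37 than in wild type, and 11 were not called (15 adjusted over the list alone; camera adjusted p = 4.53e-19, and adjusted p = 0.103 with an estimated correlation). In the Aux/IAA list 5 of 24 had a lower change (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.25e-05, and adjusted p = 0.305 with an estimated correlation). In the auxin biosynthesis list 3 of 20 did (3 adjusted over the list alone; camera adjusted p = 0.055). Of these AAO1 lost its call without any library but the second and the third wild-type NAA and the second NAA library of the other genotype (adjusted p = 0.0531 to 0.112). In the conjugation list 1 of 11 did (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00558, and adjusted p = 0.491 with an estimated correlation). That gene was GH3.3 (-1.51, adjusted p = 0.0319), and leaving out any 1 of 8 libraries ended its call (adjusted p = 0.0535 to 0.0859). Those 8 were the first, the second and the third wild-type mock, the first wild-type NAA, and in the other genotype the first and the third mock and the first and second NAA libraries. Of the other early auxin response genes 2 of 17 had a higher change (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.241), of which CRF2 lost its call without any library but the third wild-type NAA and the first NAA library of the other genotype (adjusted p = 0.0535 to 0.121). In the auxin transport list 1 of 17 had a lower one (3 lower and 5 higher adjusted over the list alone; camera adjusted p = 0.137). That gene, PILS3, lost its call without the same libraries as AAO1 (adjusted p = 0.0547 to 0.0946). No gene of the m6A list differed by limma (0 of 22; 1 higher and 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.716), nor any of 22 for auxin perception (1 higher at that level; camera adjusted p = 0.117; 0 adjusted over the list alone in both).

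**Figure D3:**
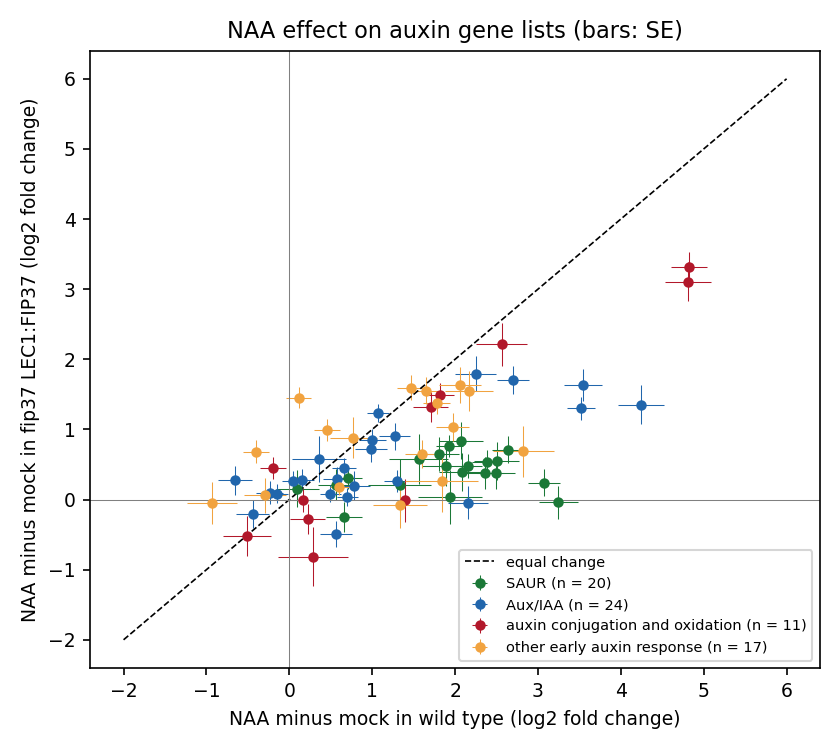
Change with NAA in wild type (x axis) and in the libraries labelled fip37 LEC1:FIP37 (y axis), as log2 fold change of RPKM + 1, for the tested genes of 4 fixed auxin lists, with bars for the SE and a dashed line for equal change. GH3.3 lay at 4.82 and 3.32, and SAUR68 rose by 3.25 in wild type while it stood at 0.258 RPKM after NAA in the other genotype.

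Under mock the libraries labelled fip37 LEC1:FIP37 had more transcripts of all 5 tested shoot meristem genes than wild type. Of 21 defence genes 4 were higher, against 2760 of all 18072. This comparison asks what the genotype changes without auxin. NATA1 (AT2G39030) stood at 1.62 ± 0.328 RPKM in wild type and 307 ± 206 there (n = 3 per group; log2 6.55, SE 0.66, adjusted p = 2.28e-05), and LOX2 (AT3G45140), a jasmonate biosynthesis gene, at 14.3 ± 1.42 and 343 ± 137 (4.43, SE 0.42, adjusted p = 1.56e-05). CUC1 (AT3G15170), a gene of organ boundaries, stood at 0.447 ± 0.0799 and 6.27 ± 0.926 (2.32, SE 0.14, adjusted p = 1e-06), and the meristem gene STM (AT1G62360) at 3.25 ± 0.0783 and 15.5 ± 1.18 (1.95, SE 0.19, adjusted p = 1.93e-05). XTH15 (AT4G14130), a cell-wall enzyme gene, was lower, at 998 ± 211 and 8.99 ± 2.96 (-6.67, SE 0.57, adjusted p = 7.89e-06). ARGOS (AT3G59900) stood at 87.0 ± 4.76 and 12.1 ± 3.21 (-2.77, SE 0.25, adjusted p = 1.08e-05) and TMK4 (AT3G23750) at 31.5 ± 2.93 and 14.9 ± 1.28 (-1.03, SE 0.11, adjusted p = 3.21e-05). In all 7004 genes were called, 2760 higher and 4244 lower, and 2039 of them differed at least 2-fold (1032 and 1007). With median-ratio scaling 3844 were higher and 3872 lower.

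In the auxin biosynthesis list 10 of 20 genes were higher under mock in the libraries labelled fip37 LEC1:FIP37 than in wild type, 3 were lower and 7 were not called (11 and 3 adjusted over the list alone). NIT2 was higher by 3.33 on the log2 scale, NIT4 by 2.37, NIT1 (AT3G44310) by 2.24 (225 ± 12.3 and 1073 ± 164 RPKM, n = 3 per group) and AAO1 (AT5G20960) by 1.56. The 3 that were lower, YUC8 (AT4G28720, -1.56), YUC5 (AT5G43890, -1.47) and AMI1 (-0.66), were named after their values were seen. Camera gave an adjusted p = 0.00168, and adjusted p = 0.489 with an estimated correlation. NIT1 to NIT3 are near-identical copies, so their single values are uncertain. In the Aux/IAA list 15 of 24 were lower and 1 was higher (15 and 1 adjusted over the list alone), with IAA17 (AT1G04250) at -1.94 and IAA7 (AT3G23050) at -1.37 (camera adjusted p = 0.000469, and adjusted p = 0.383 with an estimated correlation). In the auxin transport list 9 of 17 were lower and 2 higher, PIN7 (AT1G23080) at -1.05 among them (camera adjusted p = 0.115). In the perception list 7 of 22 were lower and 2 higher, with the receptor genes AFB1 (AT4G03190) at -1.40 and TIR1 (AT3G62980) at -0.90 (camera adjusted p = 0.217). Of the SAUR genes 7 of 20 were lower and 3 higher (camera adjusted p = 0.607), of the other early auxin response genes 7 of 17 were lower and 1 higher (camera adjusted p = 0.387), and of the conjugation genes 4 of 11 were higher (camera adjusted p = 0.0857). Of those 4, GH3.2, DAO1 and IAR3 lost their calls without any 1 wild-type mock library or the third mock library of the other genotype, DAO1 also without its first, and GH3.2 and IAR3 without its second (adjusted p = 0.0559 to 0.11). Adjusted over the list alone, the counts of the transport, perception, other early response and conjugation lists were the same, and 7 SAUR genes were lower and 4 higher.

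In the m6A list 5 of 22 genes (4244 of all 18072) were lower under mock in libraries labelled fip37 LEC1:FIP37, and FIP37 was higher. HIZ1 (AT1G32360) was at -0.62 (SE 0.13, adjusted p = 0.00221, n = 3 per group), FIO1 (AT2G21070) at -0.53 and HAKAI (AT5G01160) at -0.42, and ECT1 and ECT9 were named after their values were seen (adjusted p = 0.0312 and 0.0315). The list as a whole was not called (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.852; median -0.04, mean 0.03, test down). All 5 tested genes of the shoot meristem list were higher (5 adjusted over the list alone; camera adjusted p = 7.25e-05, and adjusted p = 0.103 with an estimated correlation). WUS (AT2G17950) of that list, under the expression filter, was named after its values were seen. It stood at 0.0262 ± 0.0227 RPKM in wild type and 1.16 ± 0.391 there. Of the root markers 4 of 8 were lower and 1 higher under mock (5 and 1 adjusted over the list alone; camera adjusted p = 0.509; median -0.60). Without the third wild-type mock library COBL9, RHD6 and SCR lost their calls (adjusted p = 0.0691, 0.0613 and 0.0625), as did COBL9 without the first (0.058) and COBL9 and RHD6 without the third mock library of the other genotype (0.0579 and 0.0788). In the photosynthesis list 9 of 18 were higher and 9 not called (11 adjusted over the list alone; camera adjusted p = 0.000401, and adjusted p = 0.513 with an estimated correlation), with RCA (AT2G39730) at 1.41 and LHCB3 (AT5G54270) at 0.99. Its RBCS and LHCB1 members are closely similar copies with uncertain values. In the ethylene list 7 of 11 were lower (8 adjusted over the list alone; camera adjusted p = 0.00445, and adjusted p = 0.539 with an estimated correlation), with the receptor genes ERS2 (AT1G04310) at -1.84 and ETR2 (AT3G23150) at -1.04. In the defence list 4 of 21 were higher, PAD3 (AT3G26830) at 2.96 and SARD1 (AT1G73805) at 2.07 among them (4 adjusted over the list alone; camera adjusted p = 0.0102, and adjusted p = 0.539 with an estimated correlation).

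With NAA, auxin response genes were lower in the libraries labelled fip37 LEC1:FIP37 than in wild type, the comparison that asks what the genotype changes under auxin. SAUR68 was lower by 3.59 on the log2 scale (SE 0.23, adjusted p = 1.02e-06, n = 3 per group), with 14.5 ± 4.80 RPKM in wild type. IAA19 stood at 131 ± 17.8 and 10.6 ± 1.78 RPKM (-3.52, SE 0.23, adjusted p = 1.01e-06). IAA3 (AT1G04240) was at -2.22 (SE 0.15, adjusted p = 1.52e-06) and GH3.3 at -0.99 (SE 0.21, adjusted p = 0.00276). AHP4 (AT3G16360), a cytokinin signalling gene, stood at 0.393 RPKM in wild type and 21.3 there (3.98, SE 0.26, adjusted p = 1.05e-06), and CYP79B2 (AT4G39950), of the tryptophan route to auxin and glucosinolates, at 12.5 and 99.2 (2.71, SE 0.53, adjusted p = 0.00157). CUC1 was at 2.56, STM at 2.48 and ARF5 (AT1G19850) at 1.74. YUC5 was at -1.84 and TMK4 at -0.91. In all 7920 genes were called, 3466 higher and 4454 lower, and 2465 differed at least 2-fold. The order of the directions turned with quantile normalization (4326 higher and 4283 lower) and without the first NAA library of that label (3758 and 3587), and with median-ratio scaling they were 4391 and 4469.

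In the SAUR list 17 of 20 genes were lower and 1 higher with NAA in the libraries labelled fip37 LEC1:FIP37 than in wild type (17 and 1 adjusted over the list alone; camera adjusted p = 1.4e-07, and adjusted p = 0.305 with an estimated correlation). In the Aux/IAA list 16 of 24 were lower and 2 higher (16 and 2 adjusted over the list alone; camera adjusted p = 1.59e-06, and adjusted p = 0.269 with an estimated correlation). In the auxin biosynthesis list 11 of 20 were higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.0382). That call was lost with median-ratio scaling (adjusted p = 0.0801), and the list's adjusted p = 0.673 with an estimated correlation. Photosynthesis genes were higher in 11 of 18 cases (12 adjusted over the list alone; camera adjusted p = 0.000243, and adjusted p = 0.491 with an estimated correlation), and all 5 tested shoot meristem genes were higher (camera adjusted p = 0.000184, and adjusted p = 0.103 with an estimated correlation). In the cell division list 5 of 9 were higher, CYCB1-1 (AT4G37490) by 1.53 among them (camera adjusted p = 0.00561, and adjusted p = 0.459 with an estimated correlation). In the ethylene list 5 of 11 were lower (7 adjusted over the list alone; camera adjusted p = 0.0416, and adjusted p = 0.673 with an estimated correlation). ERS1 and CTR1 lost their calls without the first wild-type NAA library or the first NAA library of the other genotype, and CTR1 also without the second wild-type NAA library or the third NAA library of the other genotype (adjusted p = 0.0554 to 0.112). Of the m6A genes 4 of 22 were higher, FIP37 and ECT3 (AT5G61020, 0.88) among them, and 3 lower (camera adjusted p = 0.984; median -0.07, mean 0.04). Other early auxin response genes were lower in 8 of 17 cases and higher in 2 (camera adjusted p = 0.176), transport genes in 7 of 17 and 3 (camera adjusted p = 0.457), perception genes in 6 of 22 and 3 (camera adjusted p = 0.719), and conjugation genes in 4 of 11 and 2 (camera adjusted p = 0.669). Adjusted over the list alone, the counts of the meristem, cell division, m6A, transport, perception and conjugation lists were the same, and 8 of the other early response genes were lower and 3 higher.

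Wild-type seedlings had m6A peaks in many genes, and most peaks were shared between mock and NAA. The comparison asks where auxin adds or removes m6A. The authors' lists held 5865 and 6058 nuclear peaks for the mock replicates and 4467 and 5366 for the NAA replicates. Of the first mock list 71.1% (4171 of 5865; 95% Wilson interval 69.9% to 72.3%) overlapped a peak of the second, and of the first NAA list 72.2% (3227 of 4467; 70.9% to 73.5%) overlapped a peak of the second. Over 4 ordered pairs of lists of the same treatment the overlap averaged 68.1% (60.05% to 72.2%), and over 8 pairs across treatments 68.3% (54.9% to 77.1%). Overlap across treatments was thus no lower than between replicates. Peaks found in both replicates lay in 4036 genes with mock and 3191 with NAA, of which 2603 were shared. These intervals cover counting error only.

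Few peaks were found in both lists of one treatment and in neither of the other. There were 162 such peaks with NAA (in 169 genes) and 466 with mock (in 470 genes), by coordinates of TAIR10 as the files give them. Pairing the lists across treatments gave 254 and 491, or 267 and 154, so exclusive peaks also arose between pairs of mixed treatment. With lists of equal length the order turned, to 382 with NAA and 343 with mock. Leaving out a list asks less of a peak, so both counts had to rise. Without the first mock, second mock, first NAA or second NAA list the NAA-only count was 409, 402, 751 and 592. The mock-only count was 1436, 1351, 828 and 1234. The NAA-only peak with the highest mean score of the authors lay in the 14-3-3 protein gene GRF5 (AT5G16050) at chromosome 5, 5243798 to 5244204 (fold enrichment 3.62 and 3.73). Others lay in AT3G53740 (chromosome 3, 19913719 to 19914116) and HOS15 (chromosome 5, 26860473 to 26861057). The mock-only peak with the highest mean score lay in AT1G67785 at chromosome 1, 25415871 to 25416072 (fold enrichment 5.54 and 5.53), and another of the first 10 in the flowering regulator FVE (AT2G19520) at chromosome 2, 8459253 to 8459468 (4.65 and 3.498). IAA19 carried an NAA-only peak (chromosome 3, 5265247 to 5265523, fold enrichment 1.87 and 1.70). Its RNA rose with NAA (log2 3.54), so added m6A and easier detection cannot be told apart. The reader gene ECT8 (AT1G79270) carried an NAA-only peak (chromosome 1, 29819077 to 29819411, 1.42) that also lies in NUA (AT1G79280), with no strand given to tell the genes apart, and HIZ2 (AT5G53440), with further peaks in both treatments, a mock-only one (chromosome 5, 21684959 to 21685237, 1.75). No gene of the fixed lists for auxin biosynthesis and conjugation had a peak of either kind. IAMT1 (AT5G55250), for an IAA methyltransferase and outside those lists, carried an NAA-only peak (chromosome 5, 22407584 to 22407786) and was named after its values were seen. Its RNA also rose (1.52).

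**Figure D4:**
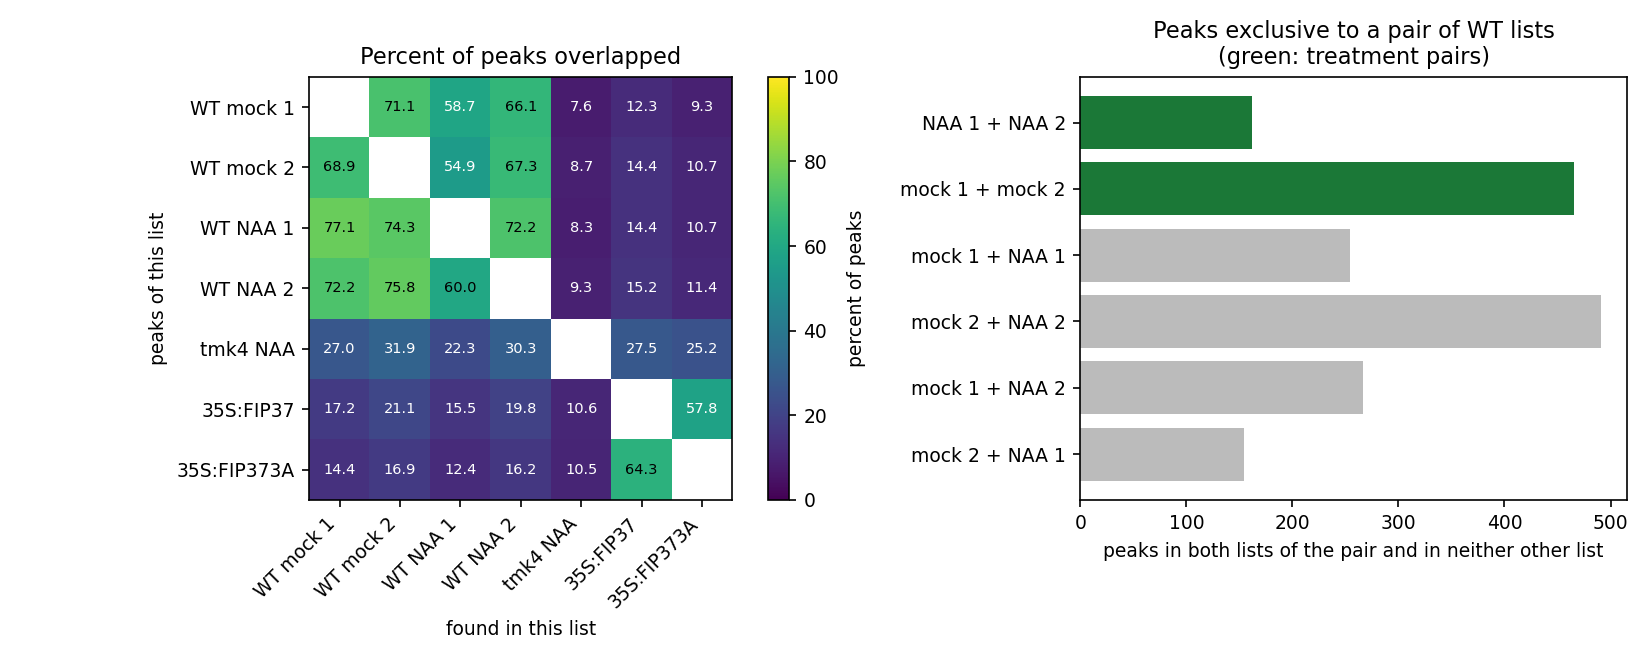
Left, percent of the peaks of each list (row) that a peak of another list (column) overlapped by at least 50% of the shorter peak; right, number of peaks found in both lists of a pair and neither list of the other pair, for each pairing of the 4 wild-type lists, with treatment pairs in green. The treatment pairs gave 162 and 466 peaks, and the mixed pairs 254, 491, 267 and 154.

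Genes with NAA-only peaks rose with NAA more often than other genes with peaks. Of 162 tested genes with such a peak 15 rose (9.26%), against 104 of 4305 others (2.42%; odds ratio 4.12, Fisher's exact test, two-sided, adjusted p = 8.04e-05 over 4 tests), and 10 fell (6.17%, adjusted p = 0.371). Examples are AT1G59740 (chromosome 1, 21968220 to 21968427; RNA log2 1.54, adjusted p = 0.000651) and AT5G35690 (chromosome 5, 13864839 to 13865041; 0.81, adjusted p = 0.00251). PKP-BETA1 (chromosome 5, 21466403 to 21466783) fell (-0.40, adjusted p = 0.0355). At matched expression the median log2 change of genes with NAA-only peaks lay 0.0481 above that of genes with peaks in both treatments (162 against 2502 genes; permutation test, two-sided, p = 0.0597). It lay 0.0579 above (p = 0.0338) for genes of at least 5 RPKM and 0.0485 above (p = 1e-05, the smallest the permutations can give) with a peak in either list, but the difference was -0.0497 (permutation p = 0.075) in the higher-scoring 50% of each list. Of 445 tested genes with mock-only peaks 8 rose (adjusted p = 0.371) and 21 fell (adjusted p = 0.715), and their median lay at -0.0611 relative to genes with peaks in both (2478 genes; permutation p = 5e-05). That difference was -0.0032 (permutation p = 0.843) in the higher-scoring 50% of each list and -0.035 (p = 0.0918) without the third wild-type NAA library, an alternative chosen after the data were seen. Genes with mock peaks and genes with none differed by 0.0068 in their change with NAA (permutation p = 0.264), and by 0.0297 (p = 0.00016) without that library.

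Of the wild-type NAA peaks found in both replicates 10.6% (341 of 3227; 9.55% to 11.7%) overlapped a peak of the tmk4 NAA list, the comparison that asks whether TMK4 is needed for m6A under auxin. The share was 4.58% in the higher-scoring 50% of each list. For wild-type mock peaks it was 9.45% (394 of 4171; 8.60% to 10.4%). In the other direction 32.9% of the 1835 nuclear tmk4 peaks (604; 30.8% to 35.1%) overlapped a peak of either wild-type NAA list, and 36.1% (662) one of either mock list. Of the 1092 genes in the tmk4 list 494 (45.2%) had a wild-type NAA peak and 573 (52.5%) a mock peak. The low share cannot be read as a loss of m6A in tmk4. The tmk4 list is 1 list with a median peak length of 100 nt, against 254 to 262 nt in wild type. Its caller is not given here, so genotype and caller cannot be told apart. Wild-type mock peaks overlapped the 35S:FIP37 list, made in that second format, in only 14.9% of cases and the 35S:FIP373A list in 11.2%, and NAA peaks did so in 17.2% and 12.6%.

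The 35S:FIP37 and 35S:FIP373A lists, which share a format, overlapped in the larger part. This comparison asks what the 3A form of FIP37 changes. Of the 4762 peaks with 35S:FIP37 57.8% (2752; 56.4% to 59.2%) overlapped a 35S:FIP373A peak, and of the 4294 peaks with 35S:FIP373A 64.3% (2759; 62.8% to 65.7%) overlapped a 35S:FIP37 peak. Peaks lay in 2273 and 2061 genes, of which 1603 were shared, 670 were found with 35S:FIP37 alone and 458 with 35S:FIP373A alone. Median enrichment scores were 2.39 and 2.37. Each line had a single list, so no spread between replicates can be set beside these shares.

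Auxin biosynthesis genes carried m6A peaks in 6 of the 7 lists, all but that of tmk4. Of the 20 tested, ASA1, ASB1 and VAS1 had wild-type mock peaks in both replicates (of all tested genes 21.6% had them; Fisher's exact test, two-sided, adjusted p = 0.732). With NAA they were ASB1, TSA1 and VAS1 (adjusted p = 1.0), none had a peak in tmk4 (adjusted p = 0.891), and NIT1, TSB1 and VAS1 had one with 35S:FIP37 (adjusted p = 0.911). With 35S:FIP373A 8 had one, namely AAO1, ASA1, ASB1, CYP79B2, NIT1, NIT2, TSA1 and TSB1 (of all tested genes 11.3% had one; odds ratio 5.24, adjusted p = 0.00538). The first of 2 such peaks in ASB1 (AT1G25220) spanned 8837281 to 8837667 on chromosome 1, and the first of 3 in CYP79B2 18525142 to 18525417 on chromosome 4. These are abundant transcripts. Labels were permuted within bins of mean expression, an alternative chosen after the data were seen. With 4.78 of 20 genes expected the call was lost (adjusted p = 0.237, other alternatives 0.00283 to 0.01). TAA1 and the YUC genes had no peak in any list, which at means up to 7.46 RPKM does not show a lack of m6A.

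Among the other gene lists, photosynthesis genes carried peaks in 8 of 18 cases in tmk4 (adjusted p = 6.73e-05), and in 16 of 18 with 35S:FIP37 (adjusted p = 6.78e-12) and with 35S:FIP373A (adjusted p = 1.42e-12). At matched expression these 3 calls were lost (adjusted p = 1.0, 1.0 and 0.471). Auxin transport genes had 35S:FIP37 peaks in 9 of 17 cases, AUX1, PIN3, PIN4 and PIN7 among them (Fisher's exact test, adjusted p = 0.000585), where 3.47 were expected at matched expression (adjusted p = 0.0177). With 35S:FIP373A they had them in 6 of 17 (adjusted p = 0.0363; 0.262 at matched expression). Defence and jasmonate genes had 35S:FIP373A peaks in 9 of 21 cases (adjusted p = 0.00208), where 2.38 were expected at matched expression (adjusted p = 0.00034), and 35S:FIP37 peaks in 3 of 21. Fisher's test called no list in the wild-type peaks (lowest adjusted p = 0.211, for SAUR genes, 0 of 20 with a mock peak in both replicates).

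Genes with wild-type m6A peaks were lower in libraries labelled fip37 LEC1:FIP37, which asks whether m6A marks transcripts that depend on FIP37. Under mock, 3904 tested genes with a peak in both mock lists had a median log2 difference of -0.20, against 0.00 for 11451 genes with none. At matched expression over the 12 libraries the difference was -0.0934 (permutation test, two-sided, p = 1e-05, the smallest possible). With bins of the wild-type mock mean, an alternative chosen after the data were seen, it was -0.0237 (permutation p = 0.00924). A peak needs wild-type reads, which favours genes higher in wild type. FIP37 was higher under this label, so the direction does not show what a loss of FIP37 does.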

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

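The test of a difference between genotypes was planned, while the tests of replicate spread and of other splits of the libraries were chosen after its result was seen. By that planned test the change with NAA differed at 306 genes between wild type and the libraries labelled fip37 LEC1:FIP37. Genes with the largest higher values there were IRT1 (difference of log2 fold changes 2.98), TIP2;3 (2.64), ATSDI1 (2.53), FRO2 (2.26), ADS1 (2.17), AT1G28660 (2.06), XTH6 (1.98), AT2G10940 (1.92), AT1G70985 (1.91) and AT4G34810 (1.79). Those with the largest lower values were GSTU25 (-3.90), GSTU24 (-3.55), UGT74E2 (-3.42), SAUR68 (-3.29), UGT73B4 (-3.06), AT1G60750 (-2.95), IAA5 (-2.89), SAUR15 (-2.83), NIT4 (-2.82) and AT2G45220 (-2.81). GSTU24 and GSTU25 are near-identical copies, so their single values are uncertain.

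Leaving out 1 library ended the calls of 8 of those 20 genes (counted among the 12 libraries, by adjusted p). IRT1 lost its call without the third wild-type mock library (0.0611), as did UGT73B4 (0.0504). GSTU25 lost it without the second or the third wild-type mock library or the second NAA library labelled fip37 LEC1:FIP37 (0.0542, 0.0611 and 0.0515). AT1G60750 lost it without the first, the second or the third wild-type mock library (0.0604, 0.0693 and 0.065) or the second mock library of the other genotype (0.0517). For AT2G45220 the same wild-type libraries (0.0616, 0.0701 and 0.101) and the first and second NAA libraries of the other genotype (0.0698 and 0.0743) decided it. ATSDI1 lost its call without any library but the third wild-type NAA library and, in the other genotype, the third mock and first NAA libraries (0.0654 to 0.129). AT2G10940 lost it without any but the third wild-type NAA library and the third mock library of the other genotype (0.0605 to 0.12). AT4G34810 lost it without any but the first and the third wild-type NAA libraries and the first NAA library of the other genotype (0.0637 to 0.13). With a pseudocount of 0.1 the calls of TIP2;3 (0.156), IRT1 (0.0921), ATSDI1 (0.0601) and AT4G34810 (0.0615) were lost, and IRT1 is listed at 0 in each NAA library labelled fip37 LEC1:FIP37.

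The pattern to weigh is that NAA called 1509 genes in wild type and 79 in the libraries labelled fip37 LEC1:FIP37. A wider spread between replicates in the latter is argued against. The model shares 1 spread per gene, the median SD was widest in wild type with NAA (0.2368, against 0.1952 and 0.1456 in the NAA and mock libraries of that label), and the change itself was smaller. The 306 genes that rose in the first and second wild-type replicates had a median log2 change of 1.12 in the third, which was held out, and of 0.0826 in the libraries labelled fip37 LEC1:FIP37 (0.04 to 0.25 in single NAA libraries), and the 275 that fell had -0.50 and -0.1022 (-0.17 to 0.05). Of 100 drawn splits of the libraries 3 gave as many genes as the 306 of the real test between genotypes, itself included, and the highest other split gave 1095, several times as many. That points to a structure of the samples, the treatment in wild type. The other two splits left wild type divided by treatment and mixed only the other genotype, so they hold the wild-type effect of NAA and give no level for chance. The 9 drawn splits of this kind gave 70 to 1095 genes and the 90 that mixed wild type 14 at most. Whether chance can be excluded for that test stays open. Also open is biology of the genotype, since starting levels differed (IRT1 stood at 0.0424 ± 0.0117 RPKM under mock there) and FIP37 went against the label, so the effect may belong to these plants rather than to a loss of FIP37.

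The tmk4 NAA list held 30 peaks on organelle chromosomes, which the comparisons did not use. The 4 wild-type lists held 2, 2, 2 and 1, and the 35S:FIP37 and 35S:FIP373A lists 0. The tmk4 list differs in format from the wild-type lists, its caller is not given in the sources used here, and no explanation was tested.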

How the results depend on the processing

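Alternatives were planned except for the fit without the third wild-type NAA library and the second mock library labelled fip37 LEC1:FIP37, tests at matched expression, bins of the wild-type mock mean, and comparisons of peaks and transcripts without the third wild-type NAA library or with median-ratio scaling, which were chosen after results were seen. Over the named genes, 5449 values kept their direction and their side of the threshold, 416 fell short of it, 2 passed it and 2 changed sign. Over the lists, 303 kept both, 35 fell short (34 of them with an estimated correlation) and 2 passed it. The values that changed sign were the change of FIP37 with NAA in the libraries labelled fip37 LEC1:FIP37, at -0.09 and -0.14 without the first mock or second NAA library (-0.14 to 0.37 over libraries left out). Unless said otherwise, the cause was not tested.

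With no expression filter the genotype difference of NAA effects counted 192 genes, and with quantile normalization 493. NAA in the libraries labelled fip37 LEC1:FIP37 called 48 genes with a filter of 5 RPKM, where fewer genes were tested, and 125 with quantile normalization. NAA in wild type called 755 in a fit of only the groups compared, where fewer libraries set the spread. Without both the third wild-type NAA and the second mock library labelled fip37 LEC1:FIP37, NAA in wild type called 4216 and the genotype difference 1469. A 2-fold minimum left 429, 50, 2039 and 2465 genes of NAA in wild type, NAA in fip37 LEC1:FIP37, and the genotype under mock and NAA, by its construction.

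Leaving out 1 library at a time gave 477 to 4119 genes for NAA in wild type, 31 to 201 for NAA in fip37 LEC1:FIP37, 5185 to 8851 and 6385 to 9112 for the genotype under mock and NAA, and 68 to 2231 for the difference of NAA effects. The labels share replicate numbers, and whether these pair the samples stays open. Deviations of same-numbered mock and NAA libraries correlated at 0.28, -0.05 and 0.30 in wild type. Among the libraries labelled fip37 LEC1:FIP37 they correlated at 0.397, -0.103 and 0.075. As a replicate block the number gave 1352, 64, 6810, 7744 and 264 genes, and 2 lists passed the threshold with it, heat shock for NAA in wild type (adjusted p = 0.0371) and cytokinin for the genotype under mock (0.046).

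For peaks, the higher-scoring 50% of each list held 1640 reproducible mock and 1224 NAA peaks, by its construction. Leaving out 1 list asks less of a peak and had to raise these counts, to 5865 to 6058 mock peaks, 4467 to 5366 NAA peaks, 402 to 751 NAA-only peaks and 828 to 1436 mock-only peaks. Lists of equal length gave 382 NAA-only and 343 mock-only peaks. The share of wild-type NAA peaks in tmk4 was 12.1% with 1 bp of overlap, 8.77% with 80%, 4.58% in the higher-scoring 50%, and 8.35% to 9.26% without 1 list. The share of 35S:FIP37 peaks in 35S:FIP373A was 55.8% with 80% overlap, 63.7% in the higher-scoring 50% and 61.4% with equal lists. Auxin biosynthesis genes lost their 35S:FIP373A call at matched expression (permutation adjusted p = 0.237), with 4.78 of 20 expected. Under mock, 10 of these 20 were higher in the libraries labelled fip37 LEC1:FIP37 than in wild type. Expression was that of the 12 RNA-seq libraries, none from the 35S lines, so abundance there was not tested.

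The change of genes with NAA-only peaks passed the threshold at 5 RPKM (0.0579) and with a peak in either list (0.0485), and it was -0.0497 (permutation p = 0.075) in the higher-scoring 50%. That of genes with mock-only peaks fell short in the higher-scoring 50% (-0.0032) and without the third wild-type NAA library (-0.035). Without that library genes with mock peaks differed from genes with none (0.0297). Under the label fip37 LEC1:FIP37 m6A genes kept their call in all alternatives, from -0.111 to -0.0237 (wild-type mock bins). RPKM gives no read totals, so what depth limits for low genes is unknown.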

Other observations

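The tests of the third wild-type NAA library, of the strength of exclusive peaks and of other splits were chosen after the results were seen, and those of the pairings of peak lists and of RNA levels were written before. Further results by list concern clock, cytokinin and defence genes. In the circadian clock list 3 of 10 genes were lower in the libraries labelled fip37 LEC1:FIP37, under mock (camera adjusted p = 0.58) and with NAA (camera adjusted p = 0.147). LUX was at -1.78 (SE 0.20, adjusted p = 4.76e-05, n = 3 per group), TOC1 at -1.30 (SE 0.17, adjusted p = 0.00011) and GI at -1.06 under mock, and LUX at -1.72 and TOC1 at -1.54 with NAA. No clock gene was called with NAA by limma in wild type (0 of 10 at an unadjusted p under 0.05; camera adjusted p = 0.704) or in those libraries (1 lower at that level; camera adjusted p = 0.0654), nor was a change called as different (0 at that level; camera adjusted p = 0.178). The third wild-type NAA library stood apart in this list too, at a median of -0.66 from the other two. PRR5, named after its values were seen, stood at 35.2, 39.9 and 13.1 RPKM in the first, the second and the third. Adjusted over the list alone, all 5 counts of the clock list were the same. Of the cytokinin genes 4 of 10 were higher under mock, ARR4 among them (camera adjusted p = 0.055; ARR7, ARR8 and CKX1 lost their calls without the second wild-type mock library, at adjusted p = 0.0555, 0.0532 and 0.127, and ARR7 and CKX1 also without others), and with NAA 2 were higher and 2 lower (camera adjusted p = 0.797; median 0.12, mean -0.02). Of the former ARR8 lost its call without any library but the first NAA library of that label (adjusted p = 0.0553 to 0.148). NAA lowered 1 of 10 in those libraries, ARR5, whose call ended without any library but the third wild-type mock and NAA libraries and the first NAA library of that label (adjusted p = 0.061 to 0.199; 2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.27), and the changes with NAA differed as a list (0 of 10 by limma, 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0256, and adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone, 1 cytokinin gene had a lower change, and the other counts of that list were the same. Of the defence genes 3 of 21 were higher and 5 lower with NAA than in wild type, with LOX2 at 3.79 and WRKY40 at -2.42 (camera adjusted p = 0.719). With NAA in wild type 1 rose and 1 fell, WRKY40 and ICS1, which lost their calls without any 1 mock library, and ICS1 also without the first or second NAA library (adjusted p = 0.055 to 0.132; camera adjusted p = 0.387; median 0.03, mean -0.02), and the changes with NAA differed as a list (0 of 21 by limma, 5 lower at an unadjusted p under 0.05; camera adjusted p = 0.00129, and adjusted p = 0.459 with an estimated correlation). Adjusted over the list alone, the counts of the defence list were the same, as were those of the heat shock list.

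Heat shock genes included 1 of 9 higher under mock in the libraries labelled fip37 LEC1:FIP37, HSP18.2 at 2.24 (camera adjusted p = 0.646; median -0.18, mean 0.20), and 3 of 9 lower with NAA (camera adjusted p = 0.242). Of these HSFA2 and HSP90.1 lost their calls without the first or the third NAA library of that label, and HSFA2 without the first or the third wild-type NAA library (adjusted p = 0.0506 to 0.0899). NAA called 0 of 9 there by limma (0 at an unadjusted p under 0.05; camera adjusted p = 0.178), and the list's changes with NAA differed (0 of 9, 1 lower at that level; camera adjusted p = 0.0166, and adjusted p = 0.673 with an estimated correlation). The comparison of genotypes with NAA and that of the changes include the third wild-type NAA library, in which the median heat shock gene lay 3.03 above the other two of its group. Cell division genes split 3 higher and 3 lower of 9 under mock (the same adjusted over the list alone; camera adjusted p = 0.609). Of the higher, CYCD3-1 lost its call without the first or second wild-type mock library or the first or the third mock library of the other genotype (adjusted p = 0.0579 to 0.0748). With NAA 1 of 9 fell in wild type, CYCA2-3, which lost its call without the first or the third mock or the first or second NAA library (adjusted p = 0.0553 to 0.0993; 4 adjusted over the list alone; camera adjusted p = 0.095), 0 of 9 were called in the other genotype by limma (2 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone; camera adjusted p = 3.28e-05, and adjusted p = 0.269 with an estimated correlation), and 1, CYCA2-3, had a higher change, a call that ended without any library but the third wild-type NAA library (adjusted p = 0.0563 to 0.151; 5 adjusted over the list alone; camera adjusted p = 0.000272, and adjusted p = 0.305 with an estimated correlation). Root markers were higher in 3 of 8 cases and lower in 1 with NAA in the libraries labelled fip37 LEC1:FIP37 than in wild type (the same adjusted over the list alone; camera adjusted p = 0.356; median -0.02, mean 0.19). The lower one, RHD6, lost its call without any wild-type mock library, or the first or second NAA library of either genotype (adjusted p = 0.0549 to 0.134). NAA called 0 of 8 root markers there by limma (2 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone; camera adjusted p = 0.833; median -0.21, mean -0.06, test up), and the list's changes differed (0 of 8, 3 higher at that level and 2 adjusted over the list alone; camera adjusted p = 0.00774, and adjusted p = 0.308 with an estimated correlation). Limma called no photosynthesis gene with NAA in either genotype (5 and 0 of 18 lower at an unadjusted p under 0.05; camera adjusted p = 0.117 and 0.156) and no shoot meristem gene (0 of 5 at that level in both; camera adjusted p = 0.896 and 0.205), and neither list differed in its change between genotypes (0 genes by limma, 1 photosynthesis gene higher at that level; camera adjusted p = 0.607 and 0.457), and all these counts were 0 adjusted over the list alone. In the ethylene, perception and m6A lists NAA called none in the libraries labelled fip37 LEC1:FIP37 by limma (2 lower, 1 higher and 0 at an unadjusted p under 0.05, and 0 adjusted over the list alone; camera adjusted p = 0.186, 0.18 and 0.209), and no ethylene gene differed (0 of 11, 3 higher at that level and 1 adjusted over the list alone; camera adjusted p = 0.209). All 15 seed and embryo markers were under the expression filter, the highest being SESA1 at 1.44 ± 1.42 RPKM in wild type with NAA, and LEC1 itself stood at 0.115, 0.238, 0.0301 and 0.126 RPKM in wild-type mock, wild-type NAA and the mock and NAA libraries labelled fip37 LEC1:FIP37. Of the flowering genes 1 of 5 was tested, SOC1, which was not called with NAA in wild type (12.04 ± 2.85 and 15.7 ± 5.92 RPKM; adjusted p = 0.54) or between genotypes under mock (adjusted p = 0.34), and FLC stood at 0.778 in wild type and 0.0801 in those libraries under mock. SESA1, LEC1, SOC1 and FLC were named after their values were seen.

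The first pattern weighed is the third wild-type NAA library, in which 1711 genes lay at least 2-fold from the other two of its group and the median heat shock gene lay 3.03 above them on the log2 scale. A mislabelled library without NAA is argued against by its SAUR genes, whose median lay 2.575 above the mock mean, and a swap with the other genotype by its FIP37 level of 11.27 RPKM. Conditions shared by replicate number 3 are argued against as the whole cause for the 755 higher genes, which deviated by a median of 0.0906 in the third mock library (68.7% in the same direction), and as a part of it they stay open. For the 956 lower genes that deviation was -0.2042 (76.9% in the same direction), between the bounds set for a shared condition and for none. A condition shared in part cannot be told apart from one in this library alone. FRK1 and NRT2.5, named after their values were seen, were far lower in that mock library (NRT2.5 at 2.43 RPKM against 18.3 and 16.5). No biological explanation was tested, since the design names none within a group.

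The second pattern is the peaks found only with NAA (162) or only under mock (466). Unequal lists may account for both counts, since another pairing of the 4 lists gave 491 such peaks, more than either treatment pair. The NAA-only peaks had a median -log10 q of 5.631, against 6.447 for all reproducible NAA peaks. For the mock-only and all reproducible mock peaks the medians were 7.728 and 7.673. The median of exclusive peaks averages both lists and that of reproducible peaks takes the first list alone. These unlike measures cannot decide nearness to the threshold. It stays open for both kinds of peak, as does a difference between lists. Transcript level stays open for the mock-only peaks. Their genes had a median difference of -0.0611 for the log2 change, but of -0.0032 (permutation p = 0.843) in the higher-scoring 50% and -0.035 (permutation p = 0.0918) without the third wild-type NAA library, and 4.72% of them fell with NAA against 4.38% of others. For the NAA-only peaks the difference was 0.0481, with permutation p = 0.0597 just over the bound written beforehand; that bound was badly set, because a p so near it excludes nothing and 15 of the 162 genes rose, so transcript level stays open. Auxin-dependent methylation stays open too and was not separated from these.

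For the other comparisons the splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each, 1 split, the real one, reached the real count: 1509 genes against 39 in the highest other split for NAA in wild type, 79 against 3 for NAA in the libraries labelled fip37 LEC1:FIP37, 7004 against 0 for the genotype under mock, and 7920 against 2 for the genotype with NAA.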
